A study of Nicotiana attenuata with 6 samples.

How the data were processed

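RNA from flower peduncles of Nicotiana attenuata, the coyote tobacco, was measured on 6 one-colour Agilent arrays, 3 for plants carrying an empty vector (EV) and 3 for irZTL, a line in which ZEITLUPE (ZTL), an F-box photoreceptor of the plant circadian clock, was silenced by RNA interference. All samples were collected at ZT0, the start of the light period, under 16 h of light and 8 h of dark. Each sample was a pool of peduncles per the labels. The labels do not say whether the pools of a group came from separate sets of plants, so the p-values measure only the spread between these pools.

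Per the labels' protocols, Cy3-labelled RNA was hybridized and the slides were scanned by the authors, who extracted spot intensities with Agilent Feature Extraction. The file headers give version 10.7.3.1 of that software and the submitters' processing notes give version 9.5. The deposited scanner files hold, per the file headers, a processed intensity for each spot on a linear scale, with background subtracted and spatial trends removed within the array, and not scaled between arrays. They also hold the median spot and background intensity and the software's flags. The authors' deposited value table holds log2 values normalized to the 75th percentile, per the series' design text. Set against the scanner files, its columns were log2 of the processed intensity minus the array's 75th percentile, with no centring per probe. Between 99.89% and 99.92% of probes on an array lay within 0.02 of the values computed here, and the column medians ran from -4.12 to -3.98. The remaining probes were not matched one by one.

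Control spots and spots marked as outliers were left out, and the spots of a probe were averaged (500 probes had 6 spots). The log2 processed intensity minus each array's 75th percentile was used for 59157 probes. As in the authors' filter, a probe was kept if it was well above background on all arrays of at least 1 group, which left 28683 probes, called measured here. Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the measured probes. A probe passed at an adjusted p under 0.05 and more than 2-fold change. Values are log2 irZTL minus EV with the standard error from limma. Where 1 group was not well above background on any array, the fold is a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. A higher floor would give a smaller fold, so the bound holds for this floor and this processing only.

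The limma step was tested on simulated data for this comparison, with the real means and spreads of the 28683 probes and 100 probes changed at each of 2 sizes. It recovered 81.0% of the changes of 1.5 log2 and 92.0% of those of 2.5 log2, with 3 false calls among 176 calls. A smaller shift given to plastid-genome probes was not counted as a change. The simulated noise was independent between probes and arrays, with no slide or replicate effect. These rates therefore do not tell how many calls in the real data come from such effects.

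Names came from the probe names, which for some probes carry the entry name of a matching protein of a related plant, such as CB23_TOBAC. A readable name was present for 364 probes, of which 200 were measured. Another 21466 probes carried a protein match by accession only and 37327 no match, and neither kind is named here as a gene. The reference table of gene symbols for this species matched 0 probe identifiers. The tests, the alternatives, the naming rule and 33 gene lists, of auxin, clock, cell wall, photosynthesis and other genes, were fixed before the data were examined. The rule took every ZTL or adagio probe, the 12 largest rises and 12 largest falls with a name whose groups did not overlap, at most 2 unnamed identifiers per direction, and up to 4 members per list. Only 4 of the 33 lists matched any probe and 2 had a measured member. Neither reached the 5 members needed for a test: heat shock and chaperones had 3, and pollen and anther markers had 1. For the lists without a measured member no result can be given. No probe name matched ZTL or an adagio protein, so the level of the silenced transcript was not analysed here. A further 12 lists were therefore written after the probe names, but no signal, had been seen. The 5 of these with at least 5 proteins measured were tested with camera, using a preset inter-gene correlation of 0.01, 1 probe per protein name without its species code and adjustment over the lists. An estimated correlation and fry were run beside it.

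The scan identifiers placed irZTL replicates 1 and 2 on slide 1 and irZTL replicate 3 with all EV arrays on slide 2, and the scan followed the slide. Slide was therefore run as a fixed block, as a random block, and by using slide 2 alone. Replicate numbers are shared between the groups in the labels. The pairing was checked in the data: the deviations from the group means correlated across probes at 0.386, 0.142 and 0.372 for replicates 1, 2 and 3, each over 0.1, so the numbers were taken as pairs. This pairing rests on the data, since the labels give only the numbers, and the main comparison has no block. The check is weak. The deviations within a group cancel out for each probe, so the 3 correlations are not independent. The deviation of irZTL replicate 3 also holds the slide difference. The pairs are therefore an assumption wherever they are used below.

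Other alternatives were quantile normalization, another set of probes for the percentile, the deposited values, other filters, the methods' t-test, other limma settings, other thresholds, and leaving out each array. Normexp background correction was run on the median signal, because the files used here hold no mean signal column. It added an offset of 50 to each intensity, which by itself makes log2 differences of dim probes smaller. Between 49.4% and 51.0% of the probes were well above background per array, and no spot was saturated. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.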

Results

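Peduncles, the stalks that carry and move the flower, were compared between irZTL and EV plants at ZT0 (3 arrays per group) to find which transcripts differed when ZTL was silenced. Of 59157 probes on the array, 28683 were well above background in all replicates of at least 1 group. Arrays were alike in depth, with 29222 to 30173 probes well above background and a 75th percentile of the processed signal between 239 and 327.

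The replicates of a group were close. The median SD between replicates was 0.14 log2 in irZTL and 0.16 in EV. Correlation of log2 values across probes was 0.994 between irZTL replicates 1 and 2, which shared slide 1, and 0.986 and 0.987 between these and irZTL replicate 3 on slide 2. It was 0.987 to 0.992 among the EV arrays, all on slide 2. Between arrays of different groups it was nearly as high, from 0.972 to 0.984. For irZTL replicate 3 it was 0.983 with EV replicate 2, little below the values with its own group. The first principal component, with 51.4% of the variance, placed the irZTL arrays at -43.3, -42.6 and -15.4 and the EV arrays at 18.0, 32.6 and 50.6. Between the irZTL arrays of the 2 slides, 1 probe had an adjusted p under 0.05 in limma and 2615 had an unadjusted p under 0.05.

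**Figure D1:**
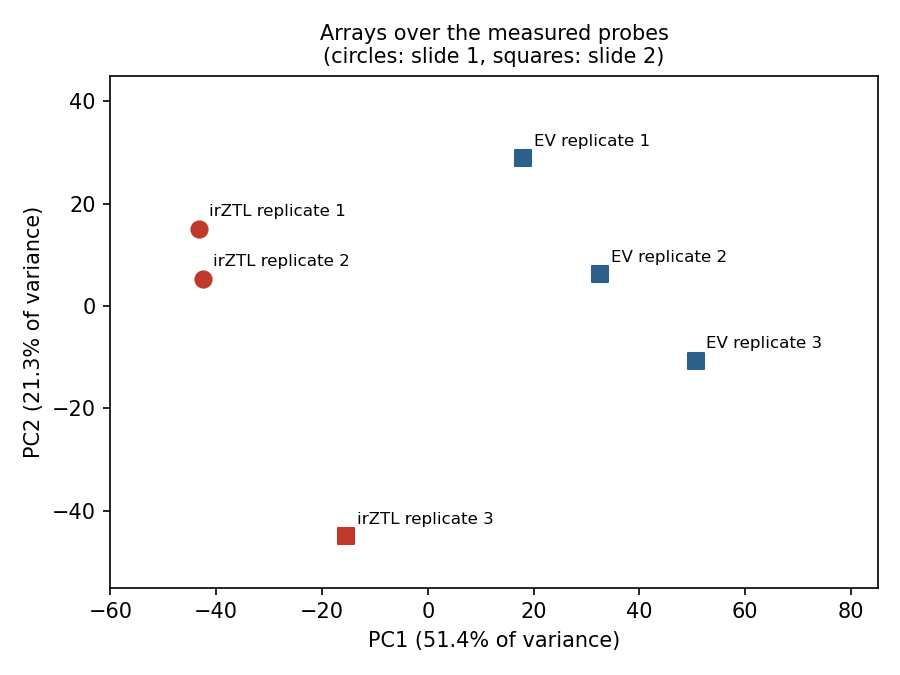
Each point is 1 array, placed by its scores on the first and second principal components of normalized log2 signal over the measured probes, with irZTL in red, EV in blue, circles for slide 1 and squares for slide 2. The irZTL arrays lie between -43.3 and -15.4 on the first component and the EV arrays between 18.0 and 50.6, and irZTL replicate 3 is at -44.9 on the second.

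CB23_TOBAC, a chlorophyll a/b-binding protein of the light-harvesting antenna, fell by 2.46 ± 0.22 log2 in irZTL (5.49-fold lower, limma adjusted p = 0.00495), from 4.92 ± 0.24 in EV to 2.46 ± 0.39 (mean ± SD, n = 3 each). RCA_SOLPN, the activase that keeps Rubisco, the carbon-fixing enzyme, active, fell by 1.34 ± 0.12 log2 (2.54-fold lower, adjusted p = 0.00540), from 5.05 ± 0.21 to 3.71 ± 0.03. Each was lower in all 3 irZTL arrays than in any EV array. The exact permutation test of each gave p = 0.1, the smallest possible with 3 against 3. Both were the only probes with a readable protein name to pass the threshold. With the methods' t-test neither passed (adjusted p of 0.0695 and 0.0624).

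Slide 1 held no EV array, so a fit with slide as a fixed block compares 1 irZTL array, replicate 3, with the EV arrays and gives the same differences as slide 2 alone. CB23_TOBAC differed there by -2.02 ± 0.21 log2 and RCA_SOLPN by -1.37 ± 0.19. Adjusted p were 0.0299 and 0.0496 with the spread estimated over all arrays, and 0.0627 and 0.105 with slide 2 alone.

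Another 4 named probes had an adjusted p under 0.05 with changes below 2-fold. They were chosen after their values were seen. PDR1_TOBAC, an ABC transporter of the pleiotropic drug resistance class, was higher in irZTL by 0.95 ± 0.10 log2 (1.93-fold, adjusted p = 0.00689), and CATA3_NICPL, a catalase that breaks down hydrogen peroxide, by 0.59 ± 0.11 (adjusted p = 0.0369). A second, brighter CATA3_NICPL probe differed by 0.22 ± 0.12 (adjusted p = 0.384). SBP2_ANTMA, a squamosa promoter-binding transcription factor, fell by 0.75 ± 0.10 log2 (adjusted p = 0.0170) and POLC2_TOBAC, a calcium-binding protein known from pollen, fell by 0.60 ± 0.12 (adjusted p = 0.0460). In each the 3 irZTL values lay on 1 side of all EV values. CATA3_NICPL and POLC2_TOBAC lost their call whichever array was left out, with adjusted p of 0.0617 to 0.129 and 0.0594 to 0.165. SBP2_ANTMA lost it without irZTL replicate 2 (0.0848), EV replicate 2 (0.0757) or EV replicate 3 (0.0701). Under the slide block, PDR1_TOBAC differed by 0.99 (adjusted p = 0.0563), CATA3_NICPL by 0.56 (0.220), SBP2_ANTMA by -0.82 (0.0934) and POLC2_TOBAC by -0.50 (0.280). On slide 2 alone their adjusted p were 0.132, 0.320, 0.174 and 0.436. With the replicate block, CATA3_NICPL had an adjusted p of 0.0523 and POLC2_TOBAC of 0.0661. Over 19 settings the adjusted p ran from 0.00310 to 0.132 for PDR1_TOBAC, 0.0230 to 0.320 for CATA3_NICPL, 0.00391 to 0.174 for SBP2_ANTMA and 0.0256 to 0.436 for POLC2_TOBAC.

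**Figure D2:**
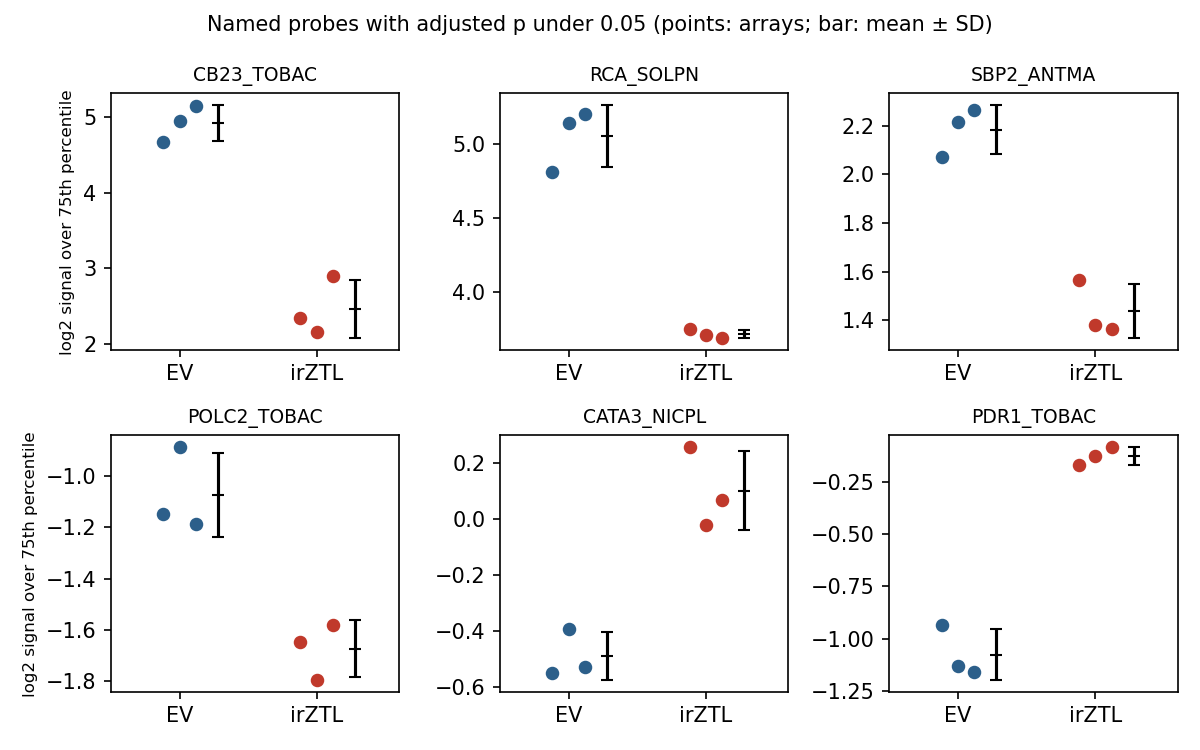
Each panel plots log2 signal relative to the array's 75th percentile for a named probe with an adjusted p under 0.05, with 1 point per array and the mean ± SD of the 3 arrays beside each group. The groups do not overlap in any panel, and CB23_TOBAC has the largest difference, from 4.92 in EV to 2.46 in irZTL.

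Of 8 measured probes for nuclear-encoded photosynthesis proteins, CB23_TOBAC and RCA_SOLPN passed the test and 6 did not. Adjusted over the list alone, CB23_SOLLC, a tomato entry for a chlorophyll a/b-binding protein, also passed, making 3. Its difference was -1.70 ± 0.37 log2, with an adjusted p over all probes of 0.0610. That p was under 0.05 in 4 of 19 settings, among them the replicate block (0.0245) and leaving out irZTL replicate 3 (0.0163), and ran from 0.0153 to 0.412. Its difference was -0.90 under the slide block (adjusted p = 0.288, and 0.412 on slide 2 alone). RBS2_NICSY, the small subunit of Rubisco, differed by -0.05 ± 0.13, CAHC_TOBAC, a chloroplast carbonic anhydrase, by -0.05 ± 0.10, and the photosystem I subunits PSAEA_NICSY and PSAEB_NICSY by -0.02 ± 0.09 and 0.07 ± 0.09. NDHM_VITVI, a subunit of the chloroplast NADH dehydrogenase-like complex, differed by 0.35 ± 0.20, and by 0.10 with normexp on the median signal. RBS2_NICSY, CAHC_TOBAC and PSAEA_NICSY were named after their values were seen. As a set of 7 proteins, with CB23_TOBAC but not CB23_SOLLC standing for their shared name, the list did not pass camera (median -0.05, mean -0.50, adjusted p = 0.381, and adjusted p = 0.742 with an estimated correlation), nor with all 8 probes (adjusted p = 0.137). Apart from CB23_TOBAC and RCA_SOLPN, the proteins of the list differed by -0.05 to 0.35, and fry was not run on these alone. With fry, which tests movement against 0 and not against other probes, the whole list had an adjusted p of 0.00133. Its median was -0.01 with slide as a fixed block, where its camera adjusted p was 0.0884.

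**Figure D3:**
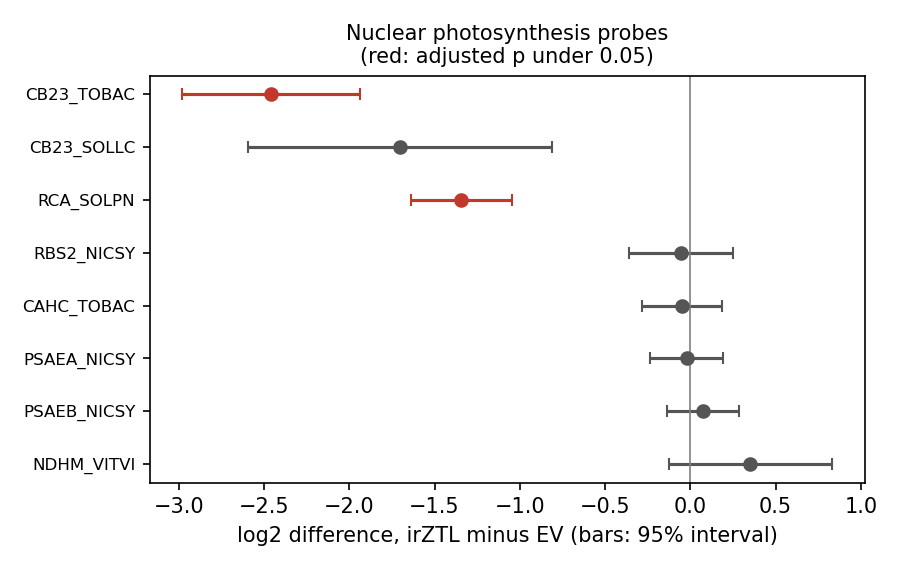
Points are the log2 difference, irZTL minus EV, of each measured probe for a nuclear-encoded photosynthesis protein, with 95% intervals from limma as bars and an adjusted p under 0.05 in red. CB23_TOBAC at -2.46 and RCA_SOLPN at -1.34 lie apart from RBS2_NICSY, CAHC_TOBAC, PSAEA_NICSY and PSAEB_NICSY, which lie between -0.05 and 0.07.

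Probes matched by name to proteins of the organelle genomes gave no call. None of 48 measured plastid-genome probes had an adjusted p under 0.05 (range -0.46 to 0.45, median -0.03). The 32 plastid proteins, at 1 probe per name, had a median of -0.01 (camera adjusted p = 0.767). Among the probes were YCF15_CUSRE at -0.46 ± 0.16 and ATPE_PELHO, an ATP synthase subunit, at 0.29 ± 0.11. These 2 were the plastid probes with an unadjusted p under 0.05 in limma. None of 9 mitochondrial-genome probes passed either (median 0.02, and 0.05 over 7 proteins, camera adjusted p = 0.640). ATP6_TOBAC, another ATP synthase subunit, differed by 0.84 ± 0.35 and NU1M_PETHY, a subunit of respiratory complex I, by 0.18 ± 0.18, and 1 mitochondrial probe, ATP6_TOBAC, had an unadjusted p under 0.05. ATP6_TOBAC differed by 0.19 under the slide block and with normexp on the median signal, and by 0.62 to 1.17 when 1 array was left out. Over the settings NU1M_PETHY ran from 0.01 to 0.34, YCF15_CUSRE from -0.57 to -0.15 and ATPE_PELHO from 0.22 to 0.35. With slide as a fixed block the plastid and mitochondrial medians over proteins were 0.13 and 0.29, each with a camera adjusted p of 0.0884.

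Protein synthesis and folding genes did not pass either, and 0 of their ribosomal and chaperone probes had an unadjusted p under 0.05 in limma. The 12 probes for cytosolic ribosomal proteins had a median of -0.11 (-0.08 over 8 proteins, camera adjusted p = 0.562), 10 of them with a negative value, among them RS3A_TOBAC at -0.17 ± 0.11 and the 3 probes of RS4_SOLTU at -0.19 ± 0.10, -0.06 ± 0.09 and -0.04 ± 0.09. The 5 chaperone probes had a median of -0.58 (camera adjusted p = 0.381). HSP71_SOLLC, a heat shock protein of the HSP70 class, differed by -1.07 ± 0.47 (adjusted p = 0.272), HSP7C_PETHY by -0.98 ± 0.63, BIP_SOLLC, an endoplasmic reticulum chaperone, by -0.58 ± 0.25 and HSP7E_SPIOL by 0.13 ± 0.11. HSP71_SOLLC had an adjusted p of 0.0291 with the replicate block, the only one of 19 settings under 0.05, and differed by -0.29 under the slide block (adjusted p = 0.892, and 0.950 on slide 2 alone). Under that block HSP7C_PETHY differed by -0.13, BIP_SOLLC by -0.26 and HSP7E_SPIOL by 0.00, and with 1 array left out HSP7C_PETHY ran from -1.52 to -0.35. Under the slide block the ribosomal and chaperone medians over proteins were -0.15 (camera adjusted p = 0.0884) and -0.13 (0.671). With an estimated correlation the camera adjusted p of the plastid, mitochondrial, ribosomal and chaperone lists was 0.930.

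Smaller lists were described and not tested, and apart from POLC2_TOBAC none of their measured probes had an adjusted p under 0.05 in limma, and 0 had an unadjusted p under 0.05. Translation factors (5 probes) had values from -0.04 to 0.09, and histones (3 probes) from -0.24 to 0.02. In defence, R1A4_SOLDE and SNAK1_SOLTU, an antimicrobial peptide, differed by 0.41 ± 0.18 and 0.33 ± 0.15. ETR1_SOLLC, an ethylene receptor, differed by -0.03 ± 0.59 and CRF2_ARATH, a cytokinin response factor, by -0.67 ± 0.33. In terpenoid and phenolic metabolism, CAMT6_TOBAC and CAMT5_TOBAC, methyltransferases of lignin synthesis, differed by 0.31 ± 0.18 and 0.21 ± 0.14, 4CL1_TOBAC by -0.19 ± 0.23 and SCS_SALOF by -0.29 ± 0.44. The only measured cell wall probe, BGAL_SOLLC, a beta-galactosidase, differed by -0.10 ± 0.12. LAT52_SOLLC, a pollen protein, differed by -0.96 ± 1.19. Differences turned in direction or reached 0 when 1 array was left out for LAT52_SOLLC (-2.10 to 0.24), ETR1_SOLLC (-0.48 to 0.71), SCS_SALOF (-0.69 to 0.11), 4CL1_TOBAC (-0.37 to 0.00) and BGAL_SOLLC (-0.18 to 0.00), so these are not settled. Under the slide block 4CL1_TOBAC differed by 0.17 and SCS_SALOF by -1.10. Over all settings CRF2_ARATH ran from -1.04 to -0.32, R1A4_SOLDE from 0.15 to 0.54, SNAK1_SOLTU from 0.20 to 0.58, CAMT6_TOBAC from 0.13 to 0.66 and CAMT5_TOBAC from 0.08 to 0.47.

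Across all measured probes, 503 passed the threshold, 258 higher and 245 lower in irZTL. All 503 had groups that did not overlap, as did 25.2% of the measured probes. Chance would give 10% if the 6 arrays were exchangeable, which the slides, and the replicate pairs if real, speak against. The change was over 4-fold for 50 higher and 54 lower probes, and over 8-fold for 9 and 16. Most carry no name: 394 had no protein match in the files, and apart from CB23_TOBAC and RCA_SOLPN the rest had a match by accession only. The largest differences in unnamed probes were those of C621082 (at least 22.0-fold higher in irZTL by the floor set here), scaffold11910 (at least 16.1-fold higher by that floor), scaffold14328 (18.9-fold lower, -4.24 ± 0.40 log2) and NA30232_32873 (15.7-fold lower, -3.97 ± 0.33), with limma adjusted p of 0.00234, 0.00281, 0.00553 and 0.00391. C621082 and scaffold11910 were not well above background on any EV array. NA30232_32873 was well above background on 2 of the 3 irZTL arrays, so its fold rests in part on a value near background. Normexp on the median signal gave smaller differences, of 2.48 log2 for C621082, 1.76 for scaffold11910, -2.85 for scaffold14328 and -2.16 for NA30232_32873. Its offset of 50 by itself makes differences of dim probes smaller. Under the slide block scaffold14328 differed by -3.40. None of these 4 passed with the methods' t-test (adjusted p of 0.0524, 0.0627, 0.0747 and 0.0686), nor scaffold11910 on slide 2 alone (0.0718).

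With slide as a fixed block, 207 probes passed (76 higher, 131 lower), 136 of them among the 503, and on slide 2 alone 62 passed (19 higher, 43 lower). The count was 302 without irZTL replicate 1, 263 without irZTL replicate 2, 249 without EV replicate 2 and 312 without EV replicate 3. Without irZTL replicate 3 the groups shared no slide, and 730 probes passed (346 higher, 384 lower). The count of all probes was 267 with normexp on the median signal, 260 with no filter on dim probes, 77 with the methods' t-test and 788 with array quality weights. These weights were lowest for irZTL replicate 3 (0.52) and highest for irZTL replicates 1 and 2 (1.90 and 1.72).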

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

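Normexp on the median signal and the list test on every probe were chosen after the files were seen, and the other alternatives before. Of 503 probes past the threshold (258 higher, 245 lower), the count was 267 (121, 146) with normexp on the median signal, 260 (126, 134) with no filter on dim probes and 77 (38, 39) with the methods' t-test, which gave 4939 probes at an unadjusted p under 0.05. It was 788 (389, 399) with array quality weights, 207 (76, 131) with slide as a fixed block, 62 (19, 43) on slide 2 alone and 1159 (603, 556) with no fold minimum. Leaving out an array gave 249 to 730 probes, 128 to 346 higher and 116 to 384 lower. With no filter more probes were adjusted over, but the unadjusted limma p of CB23_TOBAC also rose, from 1.43e-05 to 3.66e-05. Slide 2 alone and each array left out had fewer arrays, yet without irZTL replicate 3 the count rose to 730. Normexp added an offset of 50, which makes log2 differences of dim probes smaller. What moved the counts was not tested for any setting. The replicate block gave 689 (346, 343). Among named probes it ended the calls of CATA3_NICPL and POLC2_TOBAC, added those of CB23_SOLLC, HSP71_SOLLC and GLRX_SOLLC, and changed no other call. The other alternatives, among them quantile normalization (491), the deposited values (500) and slide as a random block (443), stayed within 1.5 times of 503.

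CB23_TOBAC and RCA_SOLPN had an adjusted p under 0.05 in 17 of 19 settings (range 0.000218 to 0.0695 and 0.000559 to 0.105), and were above it with the methods' t-test and on slide 2 alone. PDR1_TOBAC held in 17, SBP2_ANTMA in 12, CATA3_NICPL in 7 and POLC2_TOBAC in 6. Over the 40 probes given by name or identifier and 754 values, 43 lost a call, 11 gained one and none with a call turned in direction. Of 105 list values 1 gained a call: nuclear photosynthesis proteins with fry (median -0.0495, adjusted p = 0.00133), which tests movement against 0 and not against other probes. The slide difference within irZTL was 4 probes with quantile normalization and 0 with no filter, against 1, and 2660 and 3813 at an unadjusted p under 0.05. The median SD pooled over both groups was 0.164 with quantile normalization and 0.165 without. The methods' t-test gave 0 calls in every list at an adjusted p under 0.05, and the set tests were not run with it or with the random block. In the set tests alone, the variance trend was run without the robust option. Normexp on the mean signal was not run, and no setting was run for the ZTL transcript level. Signal over background limits the 49 higher and 27 lower probes that have only a bound.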

Other observations

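The comparison of photosynthesis probes as a check on green tissue was chosen after the result was seen. The marks of the other tests below were written before their outcomes were seen. Even so, the lower CB23_TOBAC and RCA_SOLPN signal and the distance of irZTL replicate 3 are patterns picked from these data. Some further named probes lay between an adjusted p of 0.05 and 0.1 and were picked after their values were seen. GLRX_SOLLC, a glutaredoxin that reduces disulfide bonds, differed by 0.78 ± 0.17 log2 (limma adjusted p = 0.0620) and IPIB_TOBAC by 0.80 ± 0.21 (adjusted p = 0.0965). PURA_TOBAC, an enzyme of adenine nucleotide synthesis, differed by 0.40 ± 0.10 (adjusted p = 0.0899), and SPD1_DATST, a spermidine synthase of polyamine metabolism, by -0.45 ± 0.10 (adjusted p = 0.0697). In each, the 3 irZTL arrays lay on 1 side of the 3 EV arrays. Over the settings their adjusted p ran from 0.0299 to 0.464, 0.0320 to 0.672, 0.0476 to 0.591 and 0.0272 to 0.564, and with normexp on the median signal GLRX_SOLLC, a dim probe, differed by 0.17 and IPIB_TOBAC by 0.37. The replicate block gave GLRX_SOLLC an adjusted p of 0.0484 and the slide block 0.285.

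Of the probes past the threshold, 49 that were higher in irZTL were not well above background on any EV array, and 27 that were lower were not well above background on any irZTL array. Calls were spread over the kinds of probe: 2.10% of measured genome contigs, 1.74% of scaffolds, 1.49% of probes with a protein match by accession only and 1.00% of those with a readable name passed.

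The number of probes past the threshold was weighed against chance and against the slide. Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 503 probes, and the highest other gave 1. The 4 splits that part all 3 replicate pairs include the real one, and the others of these gave 1, 0 and 0, while the 6 that part 1 pair gave 0. At an unadjusted p under 0.05 the real split had 5779 probes in limma and the others 444 to 4977, the highest with irZTL replicates 1 and 2 and EV replicate 1 on 1 side. With 10 splits no share under 0.05 can be reached. Probes called from irZTL replicates 1 and 2 against a pair of EV arrays (1077, 63 and 452 without EV replicates 1, 2 and 3) were read on the arrays left out, irZTL replicate 3 and the third EV array, which shared slide 2. The median difference in the called direction was 0.44 log2 without EV replicate 1, 1.67 without EV replicate 2 and 1.26 without EV replicate 3, and 73.2%, 84.1% and 93.6% of the probes kept their direction. The lowest, 0.44, lay above the 0.2 set for the slide as the whole cause but below the 0.5 set against it, so slide is not excluded. That setting compares unlike replicate numbers, so, if the numbers mark pairs, it also holds the difference between replicates. The only one with like numbers, EV replicate 3, passed the marks against slide as the whole cause (0.5 log2 and 75%), but it too reads 1 irZTL array. Slide and silencing are mixed in part, because 2 of the 3 irZTL arrays had a slide to themselves. They can be told apart only through the 1 irZTL array on slide 2, which does not settle it.

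The array of irZTL replicate 3, on slide 2, stood apart from irZTL replicates 1 and 2, on slide 1. Across probes, that difference had a multiple correlation of 0.387 with the differences among the EV arrays, which share a slide. Under 0.1 was set as the mark for a slide difference as the whole cause, and over 0.5 as the mark against it. Neither mark was checked on simulated arrays. The value lay between them, so slide and differences between pools cannot be told apart here. Genes are not independent replicates, and no biological explanation was tested.

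The lower CB23_TOBAC and RCA_SOLPN signal in irZTL was weighed against slide and against a smaller share of green tissue. Within slide 2 the differences were -1.37 log2 for RCA_SOLPN and -2.02 for CB23_TOBAC, where a slide difference as the whole cause would give values near 0. With slide as a fixed block the 95% intervals were -1.83 to -0.91 and -2.54 to -1.51 and both passed (adjusted p of 0.0496 and 0.0299). On slide 2 alone the same differences had adjusted p of 0.105 and 0.0627. They met the mark set against slide as the whole cause, but the mark did not allow for irZTL having 1 array on slide 2. A single array excludes nothing, so slide stays open. A smaller share of green tissue would lower other abundant photosynthesis transcripts alike, but the lowest 95% bound among RBS2_NICSY, CAHC_TOBAC, PSAEA_NICSY and PSAEB_NICSY was -0.36, above the mark of -0.67 set from the fall of RCA_SOLPN. CB23_SOLLC, left out of that check, was lower by 1.70 (95% interval -2.60 to -0.81) and would not have met the mark. The probes and the mark of the check were chosen after the values were seen, so the check decides nothing on green tissue. The values show only that the photosynthesis probes did not move alike. RBS2_NICSY, CAHC_TOBAC, PSAEA_NICSY and PSAEB_NICSY did not fall as far as RCA_SOLPN, while CB23_SOLLC did. A smaller share of green tissue stays open. A candidate explanation that stays open is a change in the regulation of these transcripts in irZTL at ZT0. It is a hypothesis found on these data and was not tested, since a single time of day was measured.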
